A study of Caenorhabditis elegans with 4 samples.

How the data were processed

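Embryos of a C. elegans strain with an integrated HLH-1::GFP transgene were assayed by ChIP-seq. Per the labels' protocols, worms were grown at 20 °C with shaking at 230 rpm and crosslinked in 2% formaldehyde, which was quenched with 100 mM Tris, and chromatin was sonicated, precipitated with an anti-GFP serum, selected by size on a gel and prepared for Illumina sequencing. The samples are 2 ChIP and 2 input libraries from separate extractions, replicates 1 and 2 of each, grouped from their descriptions.

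The data are 1 peak list of the whole series. Per the file headers and its source column, the authors called peaks with PeakSeq on WormBase WS180 coordinates, and the deposited file is named as combined, so the peaks are taken as called on both replicates together. PeakSeq's version, the aligner, the read filters and the scaling of ChIP against input are not given in the sources used here. Each peak has a start, an end and a q-value as deposited by the authors, given a second time in the attribute column with 0 differences. The largest q-value was 0.00994, so weaker regions are absent from the list. The list held 0 duplicate and 0 overlapping peaks, and neighbours were at least 200 bp apart, so nearer calls had been joined or left out before deposit. No read counts are given: the depth is unknown, and no sampling error of a single peak can be stated. Rank by q-value depends on depth and on peak width, so it orders peaks within this list and is not a measure of occupancy. The tests had been planned on a peak score; the list gives the q-value in that place, and strength was ranked by it.

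A motif search (CAGCTG and the other E-boxes, 10 classes), the genomic context of the peaks, 10 lists of tissue genes, the 2 transgene loci and the rule for named genes (hlh-1, up to 4 members per list with the strongest peak at the 5' end, 2 without one, and the genes nearest to the 10 strongest peaks) had been planned. They were not run, because they need the sequence or gene positions of WS180 and the gene table at hand is on another build (WBcel235). No gene is therefore assigned to a peak. The 10 strongest peaks are described by position instead.

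Peak widths, densities and distances were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Chromosome lengths of WS180 were not given, so each chromosome was taken to run from base 1 to the end of its last peak, 100 Mb in all. Density for the tests was counted as midpoints in whole blocks of 1 Mb, 96 blocks in all. The incomplete last block at the right end of each chromosome was left out, with its peaks. On chromosome I, 14 blocks were counted of a span of 14.998 Mb. Blocks, not peaks, were the units of the tests, because neighbouring peaks are not independent. X was compared with the autosomes by permuting block labels 100000 times, and autosomal centres with arms by permuting labels within chromosomes; both tests were two-sided. Clustering was measured as the share of peaks with another midpoint within 2 kb and compared, one-sided, with 1000 uniform placements per chromosome. Intervals of ratios are 95% percentile intervals from 2000 bootstrap resamples of blocks and cover the spread between blocks only, not between replicates. P-values of the 3 tests were adjusted by Benjamini-Hochberg.

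The tests, the stronger peaks by median q, 500-kb blocks and a 5-kb distance were fixed before the data were examined. Other limits on q, the weaker peaks, peaks of 50 bp or more, rotated labels, each autosome left out, placement within 100-kb blocks, placement with real widths and the distances of 1 kb and of 2 to 5 kb were added afterwards. The code was tested on simulated lists with as many peaks. With no difference built in, 3 of 100 lists gave a permutation p under 0.05 for X and 8 of 100 for centres. With a 1.5-fold higher density built in, 100 of 100 were found in each case, with mean ratios of 1.50 for X and 1.48 for centres. Apart from what was built in, simulated peaks were drawn independently and evenly along each chromosome. Real blocks vary along the chromosomes, with an SD of 27.4 peaks per Mb over the autosomal blocks. These rates therefore check the code and are not error rates or power of the tests on the real list. No smaller difference in density was simulated. For clustering, 20 lists of each kind were run: 100% of the clustered and 10% of the unclustered lists were called. So were 55% of the lists that differed only in having denser centres, so uniform placement also responds to density that varies along a chromosome, which placement within 100-kb blocks allows for.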

Results

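The study mapped, in embryos of the nematode Caenorhabditis elegans, the genomic regions bound by HLH-1, the worm member of the MyoD family of basic helix-loop-helix transcription factors, which acts in body wall muscle. The strain carried a transgene that makes HLH-1 fused to the green fluorescent protein (GFP), and chromatin was immunoprecipitated with a goat polyclonal antibody against GFP and sequenced (ChIP-seq). There were 2 ChIP samples and 2 samples of input DNA, the fragmented chromatin before immunoprecipitation, numbered as replicates 1 and 2. All 4 were summarised in 1 list of 13091 peaks, named as combined and taken as called on both replicates together. It holds no value of a single replicate, so no replicate error can be given. Read depth is unknown, because the list holds positions and q-values but no read counts. All positions refer to the WormBase WS180 build. The q-values are those of the authors' peak caller.

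HLH-1::GFP peaks were found on all 6 nuclear chromosomes and were mostly short. The median peak was 241 bp wide (95% bootstrap interval over peaks 237 to 244 bp), the middle 50% of peaks ran from 146 to 381 bp, and the peaks together covered 3.87% of the chromosome spans. Chromosome I had the highest number of peaks per length, 153 per Mb, followed by X with 139, III with 138, II with 128, V with 120 and IV with 112.1 peaks per Mb. Chromosome V held the most peaks in number, 2508 of the list, and chromosome III the fewest, 1898.

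Stronger peaks were wider in this list, but q depends in part on peak width, so the relation is partly built in and no test of it is given. Spearman's rho between width and −log10 q was 0.70 over the 13091 peaks (across peaks, which are not independent replicates), and it lay between 0.64 on chromosome V and 0.74 on chromosome III. None of the 1241 peaks narrower than 50 bp reached a q of 1e-10, and their median q was 0.00368. Of the 6208 peaks from 200 to under 500 bp, 22.1% reached that q. Of the 31 peaks of 2 kb or more, 96.8% did, and their median q was 1.06e-78.

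The 10 strongest peaks all lay on chromosomes I, II and III. The strongest was a region of 2962 bp on chromosome I from 9372729 to 9375690, with a q of 2.61e-240. The next was on chromosome III from 12367918 to 12370544 (2627 bp, q of 2.52e-167), and the third was on chromosome II from 4515402 to 4517750 (2349 bp, q of 5.53e-163). Chromosome III held 5 of the 10, chromosome II held 4 and chromosome I held 1. Among the 100 strongest peaks the order was different: 26 lay on X, 17 on I, 17 on III, 15 on V, 13 on IV and 12 on II. The widest peak of the list, also named after its values were seen, was 3721 bp long, on chromosome V from 724548 to 728268, but ranked only 341 by q. The second widest, 3669 bp on chromosome III from 10905906 to 10909574, ranked 129. Per the labels, the strain carries added copies of hlh-1 and unc-119 DNA in its transgene, which can raise read numbers at those loci. Their positions on WS180 were not used here, so neither the third strongest peak, the second widest, nor any other peak was compared with them, and their q-values and widths are given with that doubt.

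The first comparison asked whether the X chromosome and the autosomes carried HLH-1::GFP peaks at different densities. Over peaks of every strength within whole blocks, X carried 139 ± 14.3 peaks per Mb (SD over 17 blocks of 1 Mb). The 5 autosomes carried 129 ± 27.4 (SD over 79 blocks), a ratio of 1.08 (95% block bootstrap interval 1.01 to 1.15). This difference did not pass the two-sided permutation test of block labels (p = 0.13, Benjamini-Hochberg adjusted p = 0.13 over the 3 tests of density and clustering). The interval excludes 1 although the test was not passed. Permuting labels assumes a common spread, and the blocks of X varied less than those of the autosomes, so the 2 can differ. The difference over all peaks therefore stays undecided. Strong peaks gave a higher ratio. Peaks with a q of 1e-10 or less numbered 34.2 ± 10.5 per Mb on X and 23.04 ± 9.72 per Mb on the autosomes, a ratio of 1.49 (interval 1.26 to 1.75, permutation p = 7e-05). The whole of X against autosomal centres alone, the middle of 3 equal parts of each, gave a ratio of 1.15 for these peaks. The interval of that ratio, 0.961 to 1.38, included 1. At a q of 1e-50 or less, X carried 2.76 ± 1.99 peaks per Mb against 1.61 ± 1.43, a ratio of 1.72 (interval 1.13 to 2.497, permutation p = 0.00772). The weaker peaks went the other way in value without passing the test: the 6545 peaks weaker than the median gave a ratio of 0.95 (interval 0.883 to 1.021, permutation p = 0.272).

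The X excess therefore differed with peak strength as ranked by q, which depends in part on width. Peaks on X were also wider, with a median of 280 bp against 231 bp on the autosomes. The parts of width and strength were not separated. The ratio of X to autosomes was 1.28 times as high in the 6546 stronger peaks as in the 6545 weaker ones (permutation test of the difference itself, two-sided, p = 0.00279, chosen after the densities had been seen). Of the peaks on X, 24.5% had a q of 1e-10 or less, against 20.4% on III, 20.2% on II, 18.98% on I, 16.6% on IV and 14.4% on V. X had the highest density of such peaks of the 6 chromosomes over its whole span, 34.04 per Mb, ahead of chromosome I with 29.1 and chromosome III with 28.2. Blocks of 1 chromosome are not independent of each other. With whole chromosomes as the units, 1 X against 5 autosomes, an exact permutation test cannot go below p = 0.167, so the permutation values describe these chromosomes only.

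**Figure D1:**
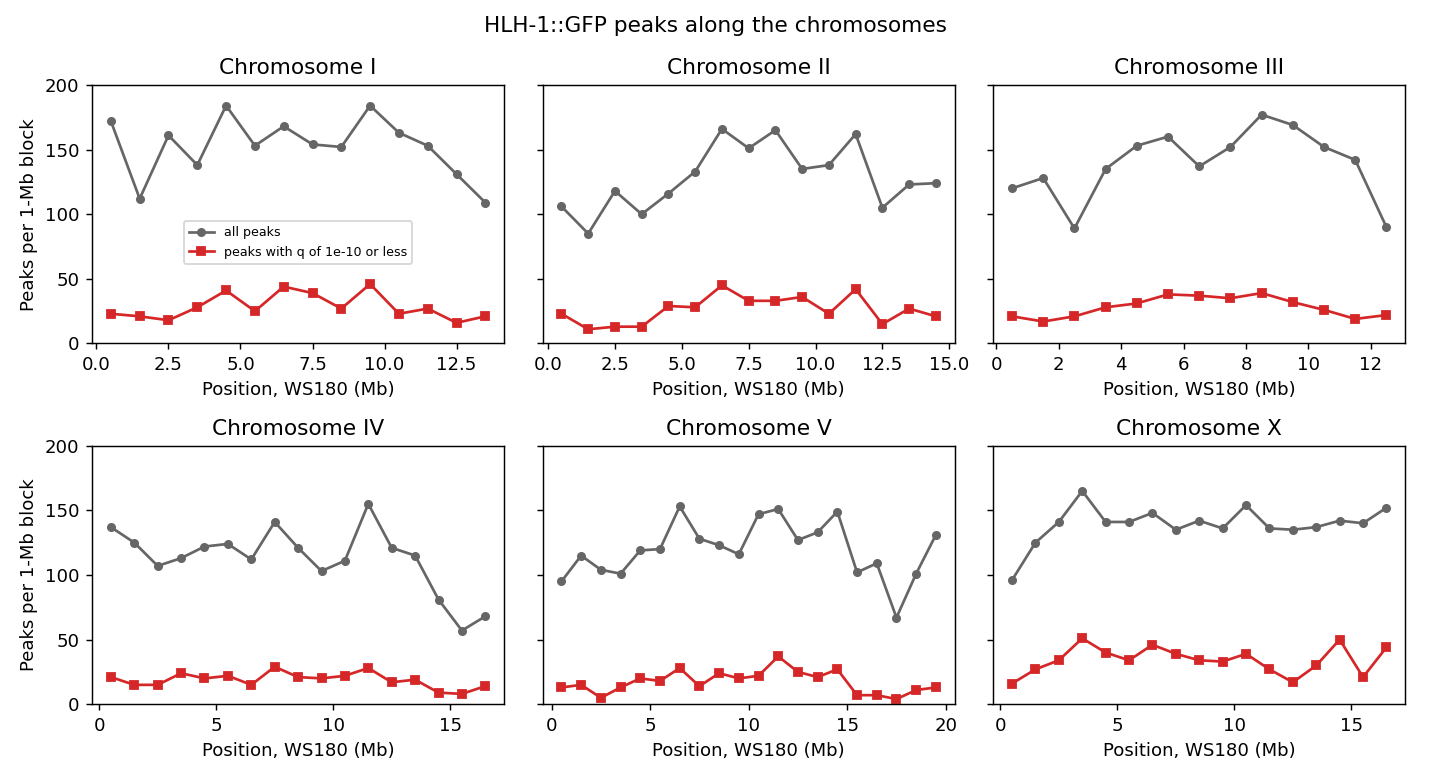
Number of HLH-1::GFP peaks in each whole 1-Mb block (vertical axis) against position in Mb on WS180 (horizontal axis) for the 6 chromosomes. Grey circles are all peaks and red squares are peaks with a q of 1e-10 or less. Lines join neighbouring blocks of 1 combined list, without error bars. Peak number falls to 57 per Mb at 15 to 16 Mb on chromosome IV and to 67 per Mb at 17 to 18 Mb on chromosome V, while the lowest block of X has 96.

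The second comparison asked whether peaks were spread evenly along the autosomes. Each chromosome was divided into 3 equal parts, the middle one called the centre and the outer ones the arms. Right arms lack the incomplete last block of their chromosome, so their densities leave out its peaks. Autosomal centres carried 143 ± 20.95 peaks per Mb (SD over 27 blocks) and arms 121 ± 27.6 (SD over 52 blocks), a ratio of 1.18 (95% block bootstrap interval 1.08 to 1.28). The centres were denser by the two-sided permutation test of block labels within chromosomes (p = 0.0001, adjusted p = 0.0003), and also when the labels were rotated along each chromosome, which keeps neighbouring blocks together (permutation p = 0.0103). The contrast was larger in value for strong peaks: those with a q of 1e-10 or less numbered 29.7 ± 9.10 per Mb in centres and 19.6 ± 8.13 in arms, a ratio of 1.52 (interval 1.29 to 1.77, rotation permutation p = 0.0009). The peaks weaker than the median had nearly equal densities, 67.0 ± 9.35 and 65.4 ± 12.7 per Mb (ratio 1.024, interval 0.949 to 1.099, permutation p = 0.542).

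The arms of single chromosomes are given as values, without a test between left and right. On chromosome II the left arm had 105 ± 13.4 peaks per Mb (5 blocks), the centre 150 ± 15.8 (5 blocks) and the right arm 130 ± 21.2 (5 blocks). On chromosome IV the right arm had 88.4 ± 28.4 peaks per Mb (5 blocks) against 124 ± 20.1 in the centre (6 blocks) and 121 ± 10.4 in the left arm (6 blocks). Chromosome V had 115 ± 19.2 in the left arm (7 blocks), 132 ± 12.7 in the centre (7 blocks) and 110 ± 28.1 in the right arm (6 blocks), and its block from 17 to 18 Mb held 4 strong peaks. On each autosome the centre was above the mean of its arms, with ratios from 1.103 on I to 1.27 on II, although the intervals of I (0.976 to 1.26) and IV (0.978 to 1.40) included 1. X was nearly flat: 135 ± 22.9 peaks per Mb in the left arm, 142 ± 7.76 in the centre and 141 ± 6.61 in the right arm, with a centre-to-arm ratio of 1.03 (interval 0.954 to 1.12). Whether X and the autosomes differ in this contrast was not tested, there being 1 X chromosome.

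**Figure D2:**
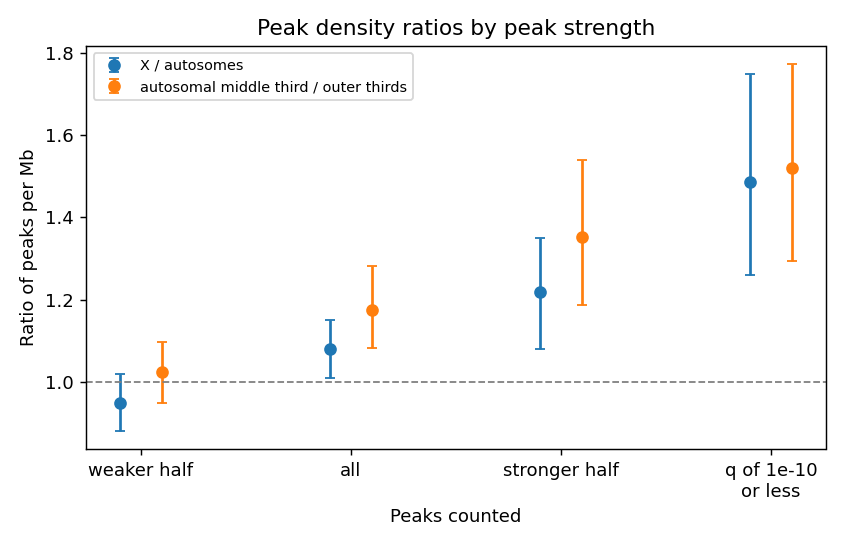
Ratio of peaks per Mb (vertical axis) for X over the autosomes (blue) and for autosomal centres, the middle of 3 equal parts, over the arms (orange), by the set of peaks counted (horizontal axis); points are ratios of block means and bars are 95% block bootstrap intervals, with the dashed line at a ratio of 1. X over autosomes goes from 0.95 in the weaker peaks to 1.49 at a q of 1e-10 or less, and centres over arms from 1.024 to 1.52.

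The third comparison asked whether peaks lay closer to each other than chance would put them. Of all peaks, 50.6% had the midpoint of another peak within 2 kb, from 48.5% on chromosome V to 54.2% on chromosome I. When the same number of midpoints was placed at random on each chromosome the mean was 40.9% and the highest of 1000 placements was 42.7% (one-sided permutation p = 0.000999, the smallest that the placements can give, adjusted p = 0.0015). Neighbouring peaks in the list were at least 200 bp apart, and placing the real peak widths with such gaps lowered the random share to 34.5%, so that the observed share was 1.47 times as high. Within 1 kb the call depended on the placement: 23.6% of peaks had a neighbour, within the range that uniform midpoints gave (mean 23.2%, highest 24.5%, one-sided permutation p = 0.244), but 1.77 times the 13.3% that the real widths with their gaps gave (one-sided permutation p = 0.000999). Widths and gaps were changed together there, so their parts cannot be separated. Among themselves, 19.4% of the peaks with a q of 1e-10 or less had another within 2 kb, against a mean of 10.04% in placements (1.93 times, one-sided permutation p = 0.000999). The random share falls with fewer peaks, and in percentage points the excess was 9.34 for these peaks and 9.69 for all peaks.

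The run with the most peaks, singled out after its values were seen, was on chromosome II. There a series of 22 peaks, each at most 2 kb from the next, extended over 23.5 kb from 6820973 to 6844435. Peaks covered 48.8% of it, 12 of the 22 had a q of 1e-10 or less, and the strongest had a q of 1.17e-43. No other run was longer than 13 peaks: runs of 13 lay on X from 16375863 to 16392595 and from 11463413 to 11481730, and on chromosome I from 14620924 to 14634480. In 1000 placements of the real widths the longest run had 7.15 peaks on average and 13 at most (one-sided permutation p = 0.000999 for the run of 22, the smallest possible). At the other end, chromosome V had no peak over 251 kb, from 2319341 to 2570498, and chromosome IV none over 147 kb, from 16509563 to 16656213. The longest distance between neighbouring midpoints in 1000 uniform placements was 131833 bp, against 251283 bp observed (one-sided permutation p = 0.000999). Both tests placed peaks over the whole chromosome, so they do not allow for density that varies along it. Placement within smaller blocks was not run for the run or the gap. Neither p-value therefore tells whether they stand out from the density around them.

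**Figure D3:**
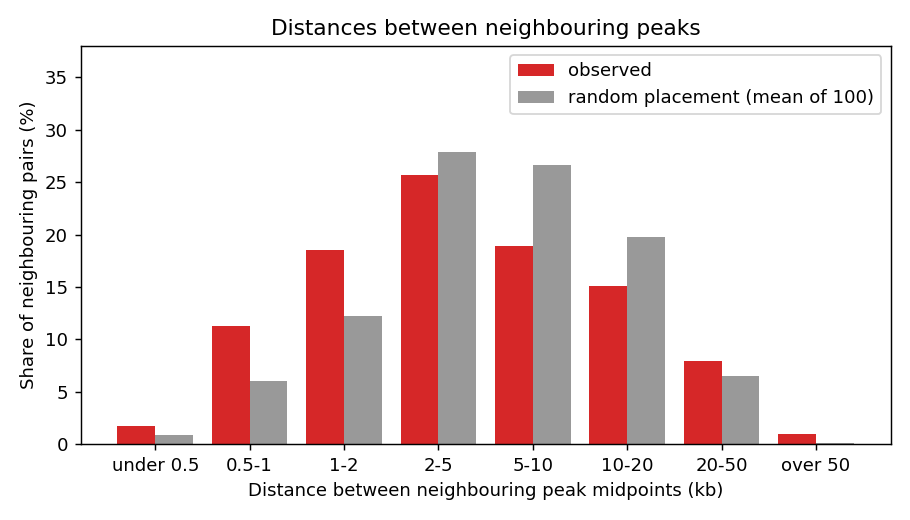
Share of neighbouring peak pairs in percent (vertical axis, from 0) by the distance between their midpoints in kb (horizontal axis, classes of unequal width), red bars for the observed list and grey bars for the mean of 100 random placements of the real peak widths with gaps of at least 200 bp; no error bars are drawn. Observed pairs exceed placed ones below 2 kb, for example 11.2% against 6.00% from 0.5 to 1 kb, and above 20 kb, and fall short between 2 and 20 kb.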

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

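Apart from 500-kb blocks, the 5-kb distance and, for density and clustering, the stronger peaks by median q, the settings here were chosen after the data had been seen. The higher density in autosomal centres kept its direction and passed the permutation test in 10 of 11 alternatives (ratios 1.15 to 1.52), including each autosome left out in turn. The exception was the set of peaks weaker than the median, with a ratio of 1.024. The clustering kept its direction in 10 of 10 alternatives and passed in 9, from 1.08 times the random share at 5 kb to 1.93 times at a q of 1e-10 or less. The exception was 1.016 times at 1 kb with uniform midpoints; with real widths and gaps, changed together, it was 1.77. X against autosomes depended on which peaks were counted: the ratio of 1.08 over all peaks missed the threshold, as it did with 500-kb blocks and without peaks narrower than 50 bp (1.08 and 1.11), but passed it at 1.22 in the stronger peaks, 1.33 at a q of 1e-05 or less, 1.49 at 1e-10 or less and 1.72 at 1e-50 or less, and was reversed in value in the weaker peaks (0.95) and at a q above 0.001 (0.947). The sets that passed are nested in each other, and blocks of 1 X chromosome are not independent. These passes are therefore not separate support for an X excess, and rotated labels were not run for X. Of 3 causes tested for the X excess in strong peaks, a few dense blocks were argued against and 2 stay open. For the exceptions among centres and clustering the cause was not tested. The median width of 241 bp moved to 347 bp in the stronger peaks and to 263 bp without peaks narrower than 50 bp, which follows from the sets themselves. No paired analysis was possible because the list holds combined peaks and no value of a single replicate; leaving out a replicate could not be run for the same reason. The alternative of clustering that needs gene ends, and all those of the motif, context, gene list and transgene results, were not run. Peaks with a q above 0.00994 are outside the list, so the weak end of each comparison is limited by that threshold, and the unknown depth limits what weak peaks can show.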

Other observations

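Of the 9 tests of explanations given here, 3 were written before the value they measure had been seen, namely placement within 100-kb blocks and both tests at 2 to 5 kb; the other 6, the placement of joined regions within 100-kb blocks and the separate counts of weak and strong neighbours were chosen after related results had been seen. Some regions stood out beyond the comparisons, all named after their values were seen. The 50-kb window with the most peaks was on chromosome II from 6800001 to 6850000, with 26 peaks where the median window had 6; in 1000 placements within each peak's own 1-Mb block the highest window also reached 26 (one-sided permutation p = 0.002). Within it, peaks were sparse up to 6820973, with 1 peak of 40 bp before that position, and then followed each other closely. The next windows held 21 peaks each, on chromosome V from 6200001 to 6250000 and from 6450001 to 6500000, and on chromosome I from 4000001 to 4050000 and from 7000001 to 7050000. Of the 2006 windows, 47 held no peak. Peaks under 50 bp wide made up 9.48% of the list and were most common on V (11.6%) and least on IV (7.45%).

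X was denser in strong peaks than the autosomes. A few very dense blocks are argued against as the whole cause, because the median block of X was 1.55 times as high as the median autosomal block at a q of 1e-10 or less (interval 1.29 to 1.86). X may be higher partly because autosomes have sparse arms. For the whole of X against autosomal centres alone the ratio fell from 1.49 to 1.15. Its interval of 0.961 to 1.38 includes both 1 and a real excess. A fall is built in there, since only the denser part of the autosomes was kept. Part against part, the centre of X had 36.3 such peaks per Mb against 29.7 in autosomal centres. The arms of X had 33.7 (left) and 32.4 (right) against 19.6 in autosomal arms. These differences were not tested, so the part played by the arms stays open. A separate scaling of X by the peak caller stays open too. The ratio for peaks with a q above 0.001 was 0.947 (interval 0.880 to 1.025), but weak peaks can cross the limit of the list in both directions, and without counts the scaling cannot be told apart from more strongly bound regions on X.

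Peaks lay closer together than random positions. Density that varies along the chromosomes on the scale of 100 kb was not enough as a cause: placed within their own 100-kb block, 43.2% of peaks on average and 44.6% at most had a neighbour within 2 kb, against 50.6% observed. Enriched regions split into calls up to 1 kb apart were not enough either: after such peaks were joined into 10373 regions, 18.7% were followed by the next within a further 1 kb, against at most 12.8% in 1000 placements along the chromosomes and 13.6% within 100-kb blocks. Any neighbour 2 to 5 kb away was found for 65.0% of peaks, against 58.7% at most in placements within 100-kb blocks. By the limit set beforehand, a share above all placements, this counted against splitting. Longer regions split into calls that far apart stay open, since they would give such neighbours too. The plot of distances between neighbouring midpoints counts only the next peak, against placements of real widths along whole chromosomes. Pairs 2 to 5 kb apart fell short there, 25.6% against 27.9%. Both the counts and the placements differ, so the 2 results can go opposite ways. Density that varies on a finer scale, such as the spacing of genes, stays open as a candidate explanation and was not tested, and no biological explanation was tested for this or the other patterns.

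Strong peaks, with a q of 1e-10 or less, more often had any neighbour within 2 kb than other peaks did, 59.4% of 2512 against 48.6% of 10579, a difference of 10.8 percentage points. Density that varies on the scale of 100 kb is argued against as the whole cause, because permuting q-values within 100-kb blocks gave at most 5.86 points. Weak calls on the shoulders of strong peaks could contribute within 2 kb, where strong peaks had a weak neighbour 7.22 points more often than other peaks (permuted maximum 5.96), but they leave out the strong neighbour that 19.4% of strong peaks had (permuted maximum 18.1%). At 2 to 5 kb the difference for any neighbour was 7.61 points (permuted maximum 5.44). By the limit set beforehand this counted against shoulder calls, which were assumed to end within 1 kb. Strong peaks had a median width of 469 bp, and whether enrichment reaches beyond the called widths cannot be seen without read counts. Counted apart at that distance, weak neighbours were in excess by 7.44 points (permuted maximum 5.03). A strong neighbour was found for 25.7% of strong peaks, above the permuted mean of 22.1% but within the range (maximum 27.7%). Because 10579 peaks were weak and 2512 strong, local clustering of any kind would show mainly as weak neighbours. The separate counts therefore do not tell shoulder calls from other clustering at that distance.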
